A study of Mus musculus with 12 samples.

How the data were processed

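Ventricles of 3 mouse hearts at postnatal day 15 were crosslinked and their chromatin sheared, per the labels' protocols. By those protocols, 1% of each heart's chromatin was kept as input. The rest was divided evenly between an antibody to Meis1 and an antibody to Hoxb13, so both precipitates would come from the same hearts. The 12 libraries form 4 groups of 3, taken from the sample titles: Meis1 precipitates and their inputs with replicate numbers 1, 2 and 3, and Hoxb13 precipitates and their inputs with the next 3 numbers. Each factor thus has its own replicate numbers and inputs, and the titles do not show that the factors shared hearts. Per the submitters' processing notes, Bowtie2 2.2.3, Picard, ChIPseeker and deepTools 1.6 were used with the mm10 build; the notes as used here give no role or order for them. The peak caller, its threshold and the way the 3 libraries of a factor were combined are not given in the sources used here.

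The deposited values were 2 annotated peak lists, 1 per factor. Each line of a list is a peak with its position, width, a signal value, a score, a summit offset, an annotation class and the nearest gene. The signal value, called peak strength in the text, is the authors' deposited value per peak. Per the file headers it has only a column number, and its place and range match the signal field of the narrowPeak format. It ran from 15.6 to 552 for Meis1 and from 17.8 to 697 for Hoxb13, and it was used only to rank or describe peaks within a list. The second deposited value, a score whose place in the narrowPeak format is that of a negative logarithm of a q-value but which the files do not name, followed the strength closely (Spearman's rho over peaks 0.988 for Meis1 and 1.000 for Hoxb13) and was not used further. Most peaks had 1 fixed width, 284 bp in 95.0% of Meis1 peaks and 396 bp in 98.8% of Hoxb13 peaks, so a Hoxb13 peak covers more sequence and overlaps a given site more easily. Of the Meis1 peaks 26 overlapped the one before them in the same list, and of the Hoxb13 peaks 1225, and each was counted as listed. The deposited promoter class was tested against the distance column: promoter peaks lay at most 997 bp (Meis1) and 999 bp (Hoxb13) from a start site, and other peaks at least 1002 bp and 1003 bp.

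Since each list covers 3 hearts with no value per library, no mean, SD or test between hearts was possible, and depth per library was unknown. The input libraries entered no comparison here.

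Gene identifiers are Entrez numbers. They were matched to a RefSeq gene table of the same build, where 9830 of the 9840 genes named by the Meis1 list and 10969 of the 10981 named by the Hoxb13 list were found, and the gene models of 99.7% and 99.9% of them overlapped. The background was the 21887 protein-coding genes of that table. A gene counted as bound if the authors had assigned at least 1 peak to it. Locus size was the gene body plus 0.5 of the gap to each neighbouring protein-coding gene (median 46.4 kb), and genes were placed in 10 strata of it, because a gene with a large locus receives more peaks by nearest-gene assignment.

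Annotation classes were compared by Fisher's exact test, two-sided, with exact binomial 95% intervals for shares and Benjamini-Hochberg adjustment over classes. Overlap between the factors required at least 1 bp, and was set against 1000 random placements of the Hoxb13 peaks, each keeping its width and offset from a randomly drawn transcription start site. The plan was to draw from the start sites of protein-coding genes; the gene table has no strand, so the 15642 start sites whose strand the peak lists give were used, which are those of genes with a peak and make the comparison stricter. Genes bound by both factors and the 19 gene lists (547 entries, each matched to a gene) were tested by an exact conditional test stratified by locus size, two-sided, with the Mantel-Haenszel odds ratio, and promoter peaks by Fisher's exact test. Some genes are members of more than 1 list, among them Des, Myocd, Myoz2 and Tead1, so the lists are not independent of each other. The difference between the factors was tested in each list by Fisher's exact test on genes bound by 1 factor alone and by the exact McNemar test. Neither of these had locus strata. All tests over genes treated each gene as independent, which neighbouring genes of a family may not be, so their p-values can be too small. List tests were adjusted by Benjamini-Hochberg over the 19 lists, with a threshold of 0.05. Where a cell of a table was 0, an odds ratio quoted from the alternatives had 0.5 added to each cell. Peak density over a list's loci was given with an interval from 2000 resamples of its genes.

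The lists, the tests and most alternatives were set before the data were examined. So was the rule for genes named in the text: 24 genes in each case, up to 3 members of each list by their strongest shared peak (by the weaker of its 2 ranks), the genes of the 10 strongest peaks of each factor, of the 10 strongest shared regions and of the 5 strongest peaks of each factor without overlap. The result for 1 of the 24 genes is not reported here. Hoxa4 and genes named only in the closing part were picked after their values were seen. Alternatives were the stronger 50% of each list, the same number of strongest peaks, promoters by peak centre, reciprocal overlap of 50%, summits within 100 bp, uniform placement, peaks moved by 10 to 100 kb, promoter peaks only, no locus strata, peaks within 10 kb of the start site and a background of genes with a promoter peak. The strongest 10%, placement on 1 start site per protein-coding gene, the overlap of equal numbers of top-ranked peaks (200 placements each), and the subsets for the promoter and difference tests were added after the data were seen. Motif tests were planned and not run, since no genome sequence was used here.

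The list test was tested on simulated data with 200 random lists of 30 genes per setting. With an odds ratio of 1 it called 3.5% of lists for Meis1 and 4.0% for Hoxb13, with an odds ratio of 2 it called 36% and 42%, and with an odds ratio of 4 it called 90.5% and 95.5%, so a list not called may still differ by an odds ratio of 2. The placement test, over 20 simulated Hoxb13 lists, gave a mean fold of 0.993 with no shared sites added, and found 499 extra shared peaks when 500 were added. The simulated lists were drawn from the same start sites and offsets as the placements, so a fold near 1 was built in. It tests the computation and not whether such placements suit real peaks. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.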

Results

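Chromatin immunoprecipitation followed by sequencing was used to map where Meis1 and Hoxb13 sat on the genome in ventricles of CD-1 mice, an outbred strain, at postnatal day 15. Meis1 is a homeobox transcription factor of the TALE class and Hoxb13 a posterior Hox protein, and the series was set up to find the binding sites of both in the heart. There were 12 libraries in 4 groups of 3, namely a Meis1 precipitate, a Hoxb13 precipitate and input chromatin paired with each. By the protocols the chromatin came from 3 hearts shared by the factors, but the titles number each factor's libraries separately. The values examined were 1 peak list per factor, each made over 3 libraries, so no spread between hearts could be given for any value below. Intervals and p-values describe the lists themselves, and read depth was unknown because the lists hold no read counts. The Meis1 list held 30534 peaks and the Hoxb13 list 22284.

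Meis1 and Hoxb13 peaks differed in their position relative to genes. Hoxb13 was found more often at gene starts, with 8980 of its peaks in the promoter class, which was 40.3% of the list (exact binomial 95% interval 39.7 to 40.9). Meis1 had 2056 promoter peaks, or 6.73% (6.45 to 7.02). Of the Meis1 peaks 16772 (54.9%) were intergenic and 10208 (33.4%) intronic, against 25.3% and 23.4% for Hoxb13. The median Meis1 peak lay 58.2 kb from the nearest transcription start site and the median Hoxb13 peak 4.55 kb. The strongest Meis1 peaks included sites 6.14 kb upstream of Myl2, which encodes the ventricular regulatory myosin light chain, and 26.6 kb upstream of Ryr2, the calcium release channel of the sarcoplasmic reticulum. The odds of a promoter position were 9.35 times higher for a Hoxb13 peak than for a Meis1 peak (95% interval 8.87 to 9.85, Fisher's exact test, two-sided, with a p-value too small for double precision). Hoxb13 peaks were also more frequent in exons (4.69% against 2.59%, adjusted exact p = 5.14e-38), 3' UTRs (2.98% against 1.16%, adjusted p = 2.02e-50), 5' UTRs (0.462% against 0.206%, adjusted p = 3.36e-07) and just downstream of genes (2.85% against 0.95%, adjusted p = 1.15e-59). Among the strongest 10% of each list, an alternative chosen after the data were seen, the odds ratio for promoters was 19.6 (71.5% of Hoxb13 peaks and 11.4% of Meis1 peaks).

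**Figure D1:**
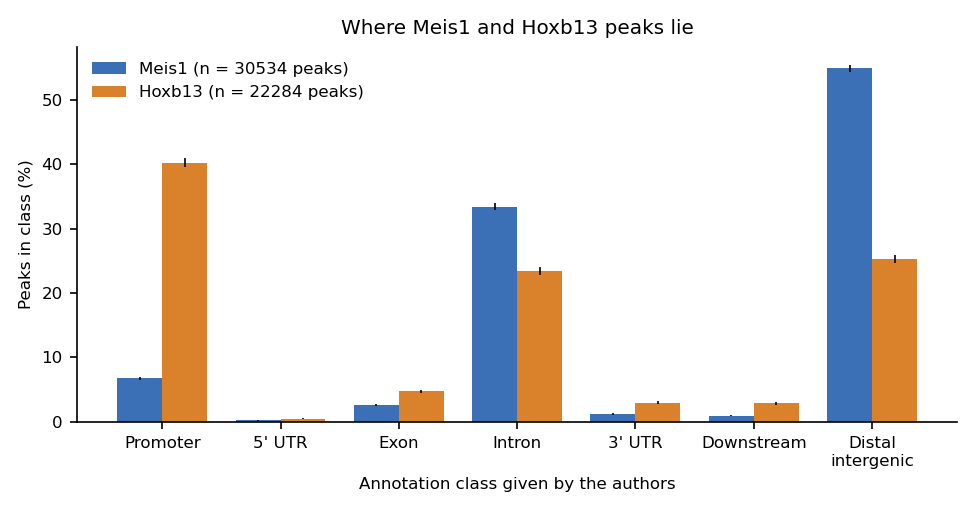
Share of peaks (%) in each annotation class the authors gave, for 30534 Meis1 and 22284 Hoxb13 peaks; error bars are exact binomial 95% intervals, which cover counting error only. The promoter class held 40.3% of Hoxb13 and 6.73% of Meis1 peaks, and the intergenic class 25.3% and 54.9%.

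The 10 strongest Meis1 peaks by the authors' strength value lay outside promoters in each case. The first (strength 552) was an intergenic site on chromosome 17 from 73022535 to 73022985 (mm10), 85.0 kb upstream of Lclat1, a lysocardiolipin acyltransferase gene that also held the peak ranked 10, in its intron 5. The second (strength 540) was the site upstream of Myl2, on chromosome 5 from 122094515 to 122094838. The others were assigned to En1, Mmp13, Plcb2, Arrdc3, Ntm, the predicted gene Gm1653 and the RIKEN cDNA gene A330074K22Rik. Among the 10 strongest Hoxb13 peaks, 3 were in the promoter class, at Stx16 (chromosome 2, 174075867 to 174076369, strength 697), Grb10 (chromosome 11, 12026187 to 12026628, strength 474) and Csnk1d (chromosome 11, 120991065 to 120991362, strength 382). The other 7 were assigned to Jun, Bahcc1, Olfr914, Iars, Tle2, Lbr and Vmn2r18, at distances of 4.15 kb for Tle2 to 192 kb for Iars. The 5 strongest peaks with no overlap with the other factor were those of Lclat1, Myl2, Mmp13, Plcb2 and Arrdc3 for Meis1 and of Stx16, Jun, Grb10, Csnk1d and Bahcc1 for Hoxb13.

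Position changed with peak strength in both lists. Of the strongest 10% of Hoxb13 peaks 71.5% were in promoters, and of the weakest 10% 18.4%. At the very top this turned, since 28.0% of the 50 strongest were in promoters, a cut chosen after the data were seen. The Meis1 promoter share went from 11.4% in the strongest 10%, with 14.6% in the next, to 2.85% in the weakest, while the median distance to a start site went from 24.8 kb to 96.2 kb.

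**Figure D2:**
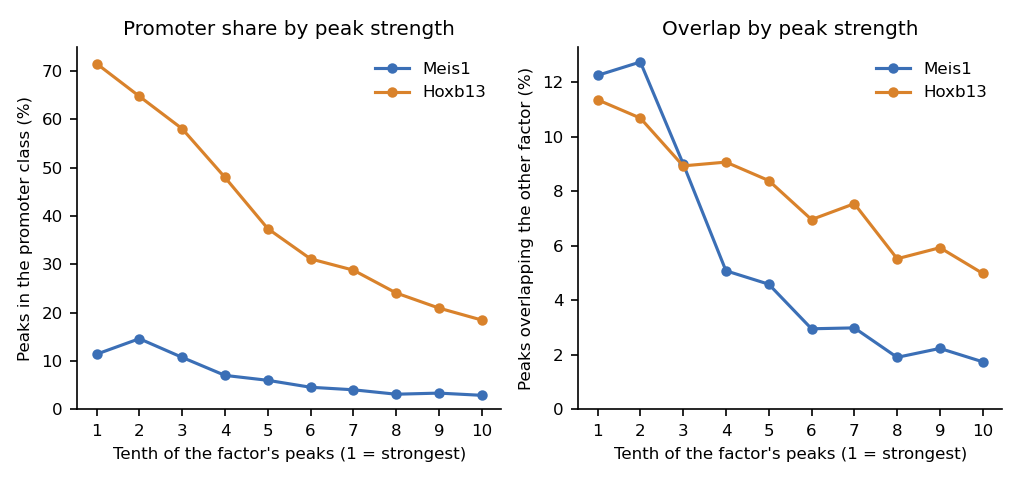
Peaks ranked by the authors' strength value and divided into 10 equal parts (x axis, 1 is strongest), with the percent in the promoter class (left) and the percent overlapping a peak of the other factor (right); each point is 1 part of 1 list. Hoxb13 promoter share fell from 71.5% to 18.4%, and overlap of Meis1 peaks with Hoxb13 peaks went from 12.3% to 1.74%.

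Whether the factors shared sites was examined by overlap of at least 1 bp. Shared sites were found at the promoters of Cdkn1b, an inhibitor of cyclin-dependent kinases, Myh6, the alpha myosin heavy chain, and Esrra, a nuclear receptor of oxidative metabolism, and 8.48 kb upstream of Atp2a2, the sarcoplasmic reticulum calcium pump. In total 1768 Hoxb13 peaks (7.93%) overlapped a Meis1 peak, and 1693 Meis1 peaks (5.54%) overlapped a Hoxb13 peak. Random placements that kept each Hoxb13 peak's offset from a transcription start site gave a mean of 3.09% (95% of placements between 2.88 and 3.32), so the observed share was 2.56 times higher (one-sided permutation test by placement, p = 0.001, the smallest that 1000 placements can give). Shared Meis1 peaks were in promoters in 44.2% of cases (exact binomial 95% interval 41.8 to 46.6) and the other Meis1 peaks in 4.54% (4.30 to 4.78). The corresponding shares of Hoxb13 peaks were 45.2% (42.9 to 47.5) and 39.9% (39.2 to 40.6). The fold depended on the placement, at 9.49 for uniform placement, 8.04 for peaks moved by 10 to 100 kb and 4.10 for 1 start site per protein-coding gene. The last was chosen after the data were seen. So were subsets by rank, in which the fold was 10.3 for the 500 strongest peaks of each list (5 shared), 5.51 for the 1000 strongest (10 shared) and 2.71 for the 20000 strongest (1460 shared). By the protocols both lists came from chromatin of the same hearts, which the titles do not show, so they may not be independent samples.

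The 10 strongest shared regions, ranked by the weaker of their ranks, were assigned to the RIKEN cDNA gene A330074K22Rik, which came first (Meis1 strength 393), and to Filip1l, Ly6c2, Txndc11, Pex2, Tle2, Gpr84, Kdm4b, Ska2 and Mb. The region at Mb, which encodes myoglobin, lay on chromosome 15, with a Hoxb13 peak from 77014165 to 77014560 (strength 51.3) and a Meis1 peak from 77014078 to 77014229 (strength 94.6), just downstream of a gene in the authors' annotation. That of Filip1l lay in its intron 1 on chromosome 16, with a Hoxb13 peak from 57391397 to 57391792 and summits 45 bp apart. Over the 1791 overlapping pairs the median distance between summits was 160 bp, so an overlap of 1 bp often joined peaks with separate summits. By the stricter alternatives, 588 Hoxb13 peaks (2.64%) had a Meis1 summit within 100 bp of theirs, 2.73 times the placements. A reciprocal overlap of 50% was met by 746 (3.35%), 2.61 times the placements. Summits were 271 bp apart at the shared site of Myh6, 235 bp at Esrra, 131 bp at Atp2a2 and 79 bp at Cdkn1b. In the fixed gene lists the strongest shared regions were those of Myh6, Tnnt2 and Csrp3 (sarcomere), Kcnh2, Atp2a2 and Slc8a1 (calcium handling and ion channels) and Esrra, Ppard and Pdk4 (fatty acid oxidation). Those of energy metabolism were Cox7a1, Ndufv1 and Cyc1 (oxidative phosphorylation), and Hk1, Egln3 and Gapdh (glycolysis and hypoxia). Among regulators they were those of Mef2a, Tead1 and Prox1 (cardiac transcription factors), Pknox1, Meis2 and Pbx3 (TALE homeobox genes), Cdkn1b, Btg2 and Lats2 (cell cycle inhibitors) and Ccnd3 alone (cell cycle activators). Among signalling genes they were those of Rcan1, Ppp3ca and Myoz2 (calcineurin and NFAT), and Insr, Nf2 and Tead1 (Hippo and growth factor signalling). Among the marker lists they were those of Col1a1, Dcn and Loxl1 (fibroblast), Egfl7, Ephb4 and Pecam1 (endothelial) and Des, Myocd and Mylk (smooth muscle and pericyte). Des is also a member of the sarcomere list, and Myocd of the cardiac transcription factor list. Rps24 and Rpl13 were the ribosomal protein genes with a shared region, and Hox, leukocyte, neuronal and hepatocyte genes had 0. Among the members of the lists the Pknox1 region ranked highest, with a Meis1 peak (chromosome 17, 31564772 to 31564973, strength 151) and a Hoxb13 peak (31564805 to 31564930, strength 44.1) at the promoter and summits 9 bp apart.

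At the level of genes, 5223 protein-coding genes had a peak of both factors, among them Ttn, Tnnt2, Actn2, Ryr2 and Atp2a2. Meis1 had a peak at 8362 of the 21887 protein-coding genes (38.2%) and Hoxb13 at 9712 (44.4%), leaving 3139 with Meis1 alone, 4489 with Hoxb13 alone and 9036 with neither. With genes compared within strata of locus size, 4109 genes with both were expected, and the odds ratio was 2.89 (95% interval 2.71 to 3.07, exact stratified test, two-sided, p = 1.88e-260). With promoter peaks alone, 1028 genes had both (odds ratio 3.42, 3.10 to 3.78).

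Meis1 peaks lay near genes of the contractile apparatus, of calcium cycling and of fat oxidation. Of 38 sarcomere genes 31 had a Meis1 peak where 14.3 were expected from locus size (odds ratio 10.8, 95% interval 4.35 to 26.6, adjusted exact p = 1.02e-07). Among calcium handling and ion channel genes, such as Ryr2 and Atp2a2, 30 of 32 had one (odds ratio 24, 4.32 to 133, adjusted exact p = 1.21e-06). Among fatty acid oxidation genes 25 of 32 had one (odds ratio 9.06, 3.48 to 23.6, adjusted exact p = 4.81e-06). Fibroblast and extracellular matrix markers had 22 of 24 (odds ratio 10.2, 2.21 to 47.1, adjusted exact p = 0.000233) and glycolysis and hypoxia genes 18 of 28 (odds ratio 3.93, 1.66 to 9.29, adjusted p = 0.00994). Cardiac transcription factors had 26 of 31 (exact test, odds ratio 3.16, 1.24 to 8.08, adjusted p = 0.0202). Hox genes were bound less often than expected, 1 of 39 against 8.22 (odds ratio 0.106, 0.0156 to 0.720, adjusted exact p = 0.00635), the exception being Hoxa4. The other 12 of the 19 lists did not pass the test. They were oxidative phosphorylation (12 of 30), cell cycle activators (15 of 38), cell cycle inhibitors (17 of 30), TALE homeobox genes (14 of 18), calcineurin and NFAT (12 of 22), Hippo and growth factor signalling (21 of 29), endothelial (16 of 26), smooth muscle and pericyte (7 of 16), leukocyte (4 of 24), neuronal (15 of 24), hepatocyte (8 of 24) and ribosomal protein genes (8 of 42). With peaks within 10 kb of the start site alone, the calls for glycolysis (odds ratio 2.71), fibroblast (2.52) and Hox genes (0.155) were lost. The Hox call was also lost in the stronger 50% of the list (0.159), so Hox genes stayed far below 1 in both. In the strongest 10%, chosen after the data were seen, TALE homeobox genes gained a call (odds ratio 8.43, 2.75 to 25.8). Calls were lost there for fatty acid oxidation (2.66), glycolysis (3.11) and Hox genes (0.195 with 0.5 added to each cell). Without locus strata 10 lists were called higher where 6 were with them, the gains being TALE homeobox, Hippo, endothelial and neuronal genes, and ribosomal protein genes were called lower. The odds ratio of calcium handling genes was 11.8 in the stronger 50%, 14.1 with the same number of strongest peaks and 6.70 with peaks within 10 kb, and each of these calls was kept. Also with calls kept, the odds ratio of fibroblast markers was 3.96 in the strongest 10%. Without locus strata it was 17.8, that of cardiac transcription factors 8.43, that of fatty acid oxidation genes 5.79 and that of Hox genes 0.0424.

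Hoxb13 peaks were found at most genes of muscle and energy metabolism and at few leukocyte and Hox genes. All 28 glycolysis and hypoxia genes, among them Hk1, Gapdh and Egln3, had a Hoxb13 peak where 12.3 were expected (adjusted exact p = 2.35e-09). Of sarcomere genes 35 of 38 had one (odds ratio 14.1, 95% interval 4.35 to 45.8, adjusted exact p = 5.86e-09) and of oxidative phosphorylation genes 28 of 30 (odds ratio 19.2, 4.71 to 78.4, adjusted p = 7.31e-09). Of fatty acid oxidation genes 30 of 32 had one (exact test, odds ratio 23.5, 5.24 to 105, adjusted p = 1.48e-08) and of ribosomal protein genes 34 of 42 (odds ratio 6.73, 3.09 to 14.6, adjusted p = 2.13e-07). Endothelial markers had 24 of 26 (odds ratio 13.5, adjusted exact p = 7.47e-06), Hippo and growth factor signalling genes 26 of 29 (odds ratio 7.23, adjusted p = 8.54e-05) and cell cycle inhibitors 24 of 30 (odds ratio 4.81, adjusted p = 0.000411). Calcium handling and ion channel genes (26 of 32), cardiac transcription factors (26 of 31), fibroblast markers (20 of 24), calcineurin and NFAT genes (18 of 22), TALE homeobox genes (15 of 18) and smooth muscle and pericyte markers (12 of 16) were also bound more often than expected, with odds ratios of 3.86 to 4.90 and adjusted exact p of 0.00188 to 0.0334. Leukocyte markers (2 of 24, odds ratio 0.137, adjusted exact p = 0.00188) and Hox genes (6 of 39, odds ratio 0.273, adjusted p = 0.00362) were bound less often. Cell cycle activators (19 of 38), neuronal genes (12 of 24) and hepatocyte genes (5 of 24, adjusted exact p = 0.0629) did not pass. In the stronger 50% of the list the calls for TALE homeobox, fibroblast and smooth muscle genes were lost, and neuronal and hepatocyte genes were called lower (adjusted exact p = 0.04996 for both). With peaks within 10 kb of the start site the smooth muscle call was lost and hepatocyte genes were called lower (adjusted exact p = 0.0294), as they were without locus strata (adjusted p = 0.0331). The strongest 10%, chosen after the data were seen, called 6 lists as higher where the whole list called 14. It lost the calls for glycolysis and hypoxia (odds ratio 2.39, adjusted exact p = 0.284), Hox (adjusted p = 0.151) and leukocyte genes (adjusted p = 0.35), so that 0 lists were called lower. The calls for cell cycle inhibitors, cardiac transcription factors, TALE homeobox, calcineurin and NFAT, Hippo, fibroblast and smooth muscle genes were lost as well. Some odds ratios moved although the calls were kept. In the stronger 50% they were 7.69 for fatty acid oxidation, 7.93 for sarcomere, 7.52 for endothelial, 10.8 for glycolysis, 0.236 for leukocyte and 0.0691 for Hox genes. Without locus strata they were 10.9 for Hippo and 6.28 for TALE homeobox genes. With peaks within 10 kb they were 6.28 for fatty acid oxidation and 7.14 for endothelial genes. In the strongest 10% they were 4.98 for fatty acid oxidation, 3.44 for sarcomere, 4.95 for oxidative phosphorylation, 5.72 for endothelial and 16.0 for ribosomal protein genes.

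**Figure D3:**
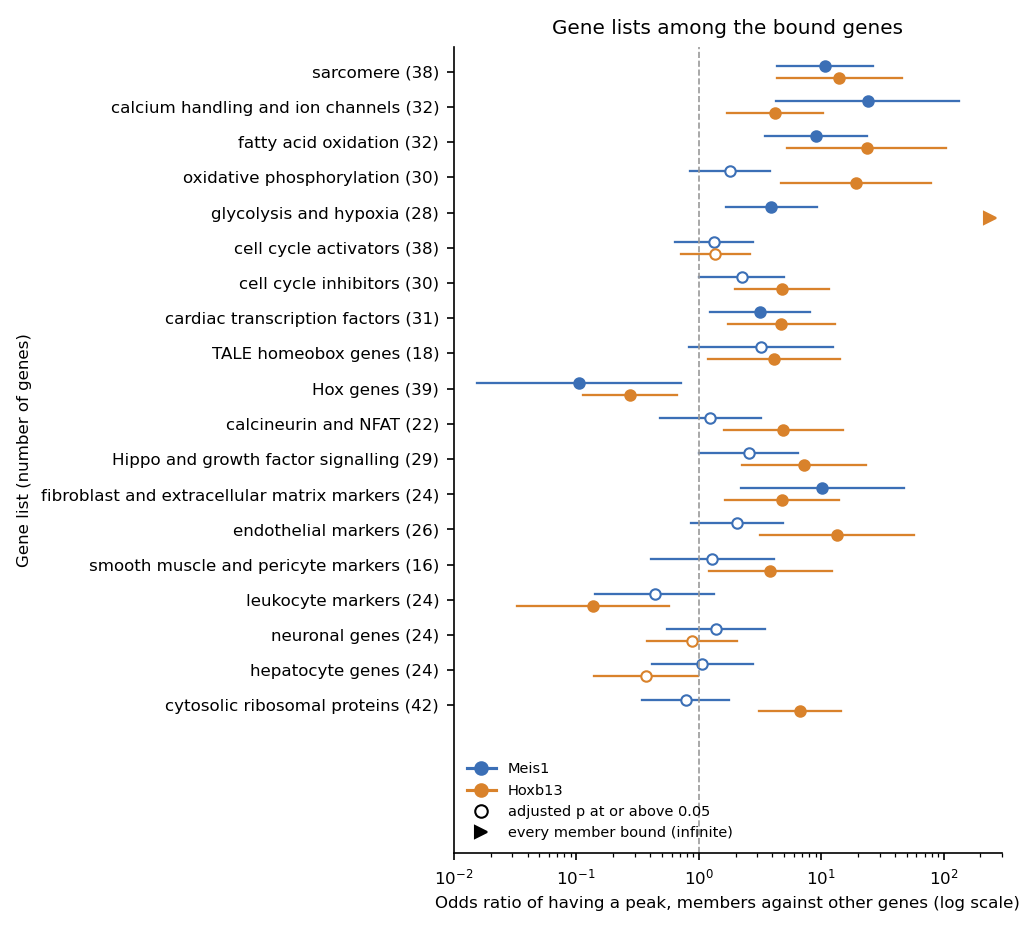
Odds ratio (log axis) of having at least 1 peak for members of each fixed gene list against other protein-coding genes, within strata of locus size; points are Mantel-Haenszel estimates with 95% intervals, open points did not pass the adjusted threshold of 0.05, and the triangle marks a list with every member bound. The Meis1 odds ratio of calcium handling and ion channel genes was 24, and ribosomal protein genes were above 1 for Hoxb13 (6.73) with a Meis1 interval of 0.343 to 1.78.

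At promoters, both factors were found more often than expected at sarcomere, fatty acid oxidation, TALE homeobox and calcium handling genes. The same held for cardiac transcription factors, glycolysis and hypoxia genes, and calcineurin and NFAT genes. A Meis1 promoter peak was present at 15 of 38 sarcomere genes (39.5% against 8.16% of all protein-coding genes, odds ratio 7.39, 95% interval 3.58 to 14.8, adjusted exact p = 2.16e-06), 8 of 18 TALE homeobox genes (odds ratio 9.04, adjusted p = 0.000255), 11 of 31 cardiac transcription factors (odds ratio 6.22, adjusted p = 0.000180) and 9 of 32 fatty acid oxidation genes (odds ratio 4.42, adjusted p = 0.00372). Calcineurin and NFAT, glycolysis and hypoxia, and calcium handling genes also passed, and no list was called lower. Hox genes had 0 of 39 where 3.18 were expected (adjusted exact p = 0.138). Leukocyte and hepatocyte genes each had 0 of 24 (adjusted exact p = 0.375 for both). Even 0 bound genes did not pass in these lists, so the test could hardly call a list lower for Meis1. A Hoxb13 promoter peak was present at 28 of 30 oxidative phosphorylation genes (93.3% against 30.7%, odds ratio 31.7, 7.99 to 275, adjusted exact p = 1.76e-11), 24 of 28 glycolysis and hypoxia genes (odds ratio 13.6, adjusted p = 2.36e-08), and 31 of 42 ribosomal protein genes (odds ratio 6.38, adjusted p = 7.04e-08). One was also present at 24 of 30 cell cycle inhibitors (odds ratio 9.05, adjusted exact p = 1.71e-07) and 27 of 38 sarcomere genes (odds ratio 5.55, adjusted p = 1.15e-06). Cardiac transcription factors had 18 of 31 (odds ratio 3.13, adjusted exact p = 0.00279) and calcium handling genes 18 of 32 (2.90, adjusted p = 0.00413). Calcineurin and NFAT genes had 14 of 22 (odds ratio 3.95, adjusted exact p = 0.00279). In all, 12 lists were higher and 4 lower for Hoxb13 by Fisher's exact test, the 4 being hepatocyte (0 of 24), Hox (3 of 39), leukocyte (1 of 24) and neuronal genes (2 of 24). When the background was limited to genes with a promoter peak of either factor, which asks which factor was present, the Meis1 call for sarcomere genes was kept (odds ratio 3.21, adjusted exact p = 0.0364) and 0 lists were called for Hoxb13. Most genes of that background have a Hoxb13 promoter peak by construction (6725 genes had one, and 1786 a Meis1 one). A list could therefore hardly be called higher for Hoxb13 there. In the stronger 50% of each list, chosen after the data were seen, the Meis1 call for calcineurin and NFAT genes (adjusted exact p = 0.101) and the Hoxb13 call for TALE homeobox genes (adjusted p = 0.185) were lost. Meis1 gained a promoter call for oxidative phosphorylation genes there (odds ratio 3.84, adjusted exact p = 0.0238) and with the same number of strongest peaks, also chosen afterwards (3.23, adjusted p = 0.0435), where the whole list gave 6 of 30 (2.82, adjusted p = 0.0671). In the strongest 10%, also chosen afterwards, 3 lists were called higher for Meis1, namely sarcomere, calcium handling (odds ratio 9.89) and TALE homeobox genes (26.7), and 4 for Hoxb13. The 4 were ribosomal protein (19.2), oxidative phosphorylation (6.11), fatty acid oxidation (3.99) and Hippo genes (3.71). No list was called for both factors there. Sarcomere, fatty acid oxidation and TALE homeobox genes each lost the call of 1 factor there, namely Hoxb13 at sarcomere genes (odds ratio 2.15, adjusted exact p = 0.234) and at TALE homeobox genes (0.835, adjusted p = 1), and Meis1 at fatty acid oxidation genes (2.21, adjusted p = 0.641). The 4 lower Hoxb13 calls were lost there too (adjusted exact p = 0.234 for Hox genes and 0.508 for each of the others). Among calls kept in the stronger 50%, Hoxb13 odds ratios fell to 7.05 for glycolysis, 3.34 for sarcomere and 3.33 for endothelial genes, and with 0.5 added to each cell they were 0.0420 for Hox and 0.0678 for neuronal genes.

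The factors differed in 3 lists by the test of the difference itself. Among oxidative phosphorylation genes, which include Cox7a1, Ndufv1 and Cyc1, 16 had Hoxb13 alone, 0 had Meis1 alone and 12 had both, a split that differed from that of other genes (odds ratio at least 2.70 by its 95% lower bound, Fisher's exact test, adjusted p = 0.00365). Among ribosomal protein genes 27 had Hoxb13 alone and 1 had Meis1 alone (odds ratio 19, 3.13 to 778, adjusted exact p = 0.000164), and among glycolysis and hypoxia genes 10 had Hoxb13 alone and 0 had Meis1 alone (lower bound 1.57, adjusted p = 0.0448). The exact McNemar test within each list gave adjusted p of 0.000290, 4.11e-06 and 0.0124. Neither test took account of locus size. From locus size, Meis1 and Hoxb13 peaks were expected at 8.31 and 11.8 oxidative phosphorylation genes, 9.51 and 16.5 ribosomal protein genes, and 10.5 and 12.3 glycolysis and hypoxia genes. Over all protein-coding genes the bound counts were 8362 and 9712. How much of the lean to Hoxb13 comes from locus size was not tested. The other 16 lists did not pass, and sarcomere genes were mostly bound by both (30 of 38). The glycolysis call was lost in the stronger 50% of each list (odds ratio 2.15, adjusted exact p = 0.265), where fibroblast markers were called in favour of Meis1 (0.0894, adjusted p = 0.0275), and with the same number of strongest peaks per factor (adjusted p = 0.129). In the strongest 10% the oxidative phosphorylation call was lost too (odds ratio 3.34, adjusted exact p = 0.217), and calcium handling genes (0.157) and TALE homeobox genes (0.0580) were called in favour of Meis1 (adjusted p = 0.0306 for both). The ribosomal protein call was kept, at 12.6 in the stronger 50% and 55.2, with 0.5 added to each cell, in the strongest 10%. These alternatives were chosen after the data were seen.

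Among the regulators themselves, Meis1 peaks were found at its own gene and at that of its relative Meis2. The Meis1 gene (Entrez 17268) had 8 Meis1 peaks, the strongest in its promoter 292 bp from the start site (chromosome 11, 19018575 to 19018677, strength 97.4), and 3 Hoxb13 peaks. Meis2 had 8 Meis1 and 3 Hoxb13 peaks. The Hoxb13 gene had 0 peaks of either factor.

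Peaks differed between single genes of the cell cycle and of growth signalling. Cdkn1b (Entrez 12576) carried a shared promoter site, with a Meis1 peak on chromosome 6 from 134920263 to 134920546 (strength 61.8) and a Hoxb13 peak from 134920286 to 134920681 (strength 28.2). Cdkn1a had 1 Meis1 and 2 Hoxb13 peaks that did not overlap, and the Meis1 peak ranked 17616 by strength. Cdkn2a and Cdkn2b had 2 and 1 Meis1 peaks and 0 Hoxb13 peaks, while the cyclin gene Ccnd2 had 1 Hoxb13 promoter peak and 0 Meis1 peaks. The Cdkn2b peak was distant and weak, 156 kb from the start site in an intron of another gene, ranking 28376 of 30534. The stronger Cdkn2a peak lay 38.5 kb from the start site and ranked 13466. Erbb4, a neuregulin receptor gene, had 15 Meis1 peaks, the strongest at 29.1, and 0 Hoxb13 peaks. Such counts are not corrected for locus size. Over the Hippo and growth factor list, which holds Erbb4, Meis1 peaks per 100 kb were 0.860 times those of other genes, and 0.826 times without Erbb4. Yap1, a Hippo pathway effector, had 1 of each. Among calcineurin genes, the catalytic subunit gene Ppp3ca had 5 peaks of each factor and the inhibitor gene Rcan1 had 5 Meis1 peaks, the strongest at its promoter (110), and 3 Hoxb13 peaks.

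Hoxb13 peaks were numerous at sarcomere genes and at some calcium handling genes. Ttn (Entrez 22138), which encodes the giant sarcomere protein titin, had 93 Hoxb13 peaks and 11 Meis1 peaks. Of the sarcomere genes, Myh6 had 15 and 1, Myh7 had 15 and 2, Tnnt2 had 10 and 6, and Actn2 had 9 and 5. Of the calcium handling genes, Atp2a2 (Entrez 11938) had 29 and 4. Ryr2 had 20 Hoxb13 and 10 Meis1 peaks over a locus of 1187 kb, or 1.68 Hoxb13 peaks per 100 kb. The strongest Hoxb13 peak of Ttn lay in intron 2 (chromosome 2, 76977714 to 76978109, strength 64.5) and overlapped a Meis1 peak. The strongest peaks near Ryr2 (382, chromosome 13, 12133513 to 12133850), Atp2a2 (324, chromosome 5, 122521158 to 122521397) and Tnnt2 (179, chromosome 1, 135836021 to 135836243) on the Meis1 list ranked 14, 35 and 263 of that list, the last at the promoter. Among metabolic regulators, Ppargc1a had 12 Meis1 and 5 Hoxb13 peaks, and Ppara had 3 and 2, with a shared intergenic site about 10.5 kb upstream (Meis1 strength 171). Meis1 peaks per 100 kb of fatty acid oxidation genes were 2.03 times those of other genes, and 2.58 times without Ppargc1a. The Meis1 peaks of Ppargc1a were thus less dense than those of the rest of that list. Of the cardiac transcription factors, Gata4 had 6 Meis1 and 12 Hoxb13 peaks and Nkx2-5 had 5 and 2. Peaks per 100 kb of sarcomere gene locus were 8.07 for Hoxb13 and 3.24 for Meis1, against 0.713 and 0.904 for other genes. For calcium handling and ion channel genes, with 181 Hoxb13 and 196 Meis1 peaks, they were 1.70 and 1.84, which is 2.36 times (95% interval 1.35 to 4.15) and 2.04 times (1.68 to 2.66) those of other genes, and the Hoxb13 ratio without Atp2a2 was 2.00.

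**Figure D4:**
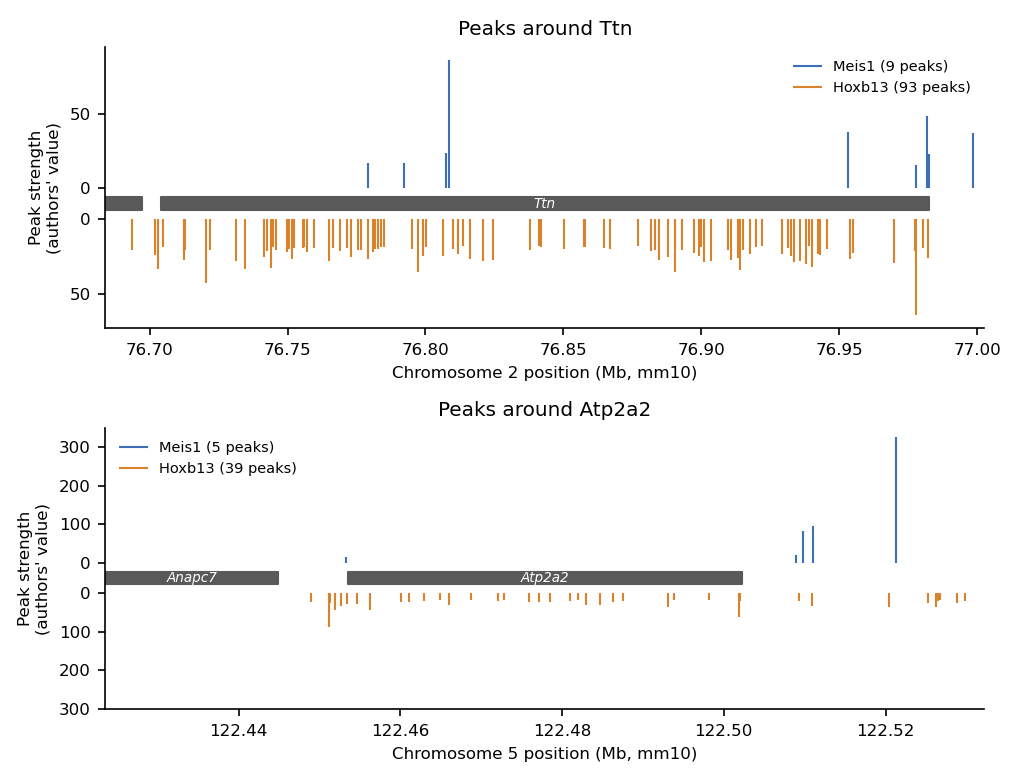
Peaks around Ttn (chromosome 2, 76683980 to 77002557) and Atp2a2 (chromosome 5, 122423513 to 122532225); the x axis is position in Mb (mm10), vertical lines are peaks drawn up for Meis1 and down for Hoxb13 with length equal to the authors' strength value, and grey boxes are protein-coding genes. In these windows there were 93 Hoxb13 and 9 Meis1 peaks around Ttn, and 39 and 5 around Atp2a2, where the strongest Meis1 peak reached 324.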

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

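The tests of X chromosome, locus size and ribosomal protein promoters reported here were chosen after their results were seen; the others were written first. The lists picked out for a closer look were the 3 in which the factors differed by the test of the difference, namely oxidative phosphorylation (odds ratio 23.2 with 0.5 added to each cell), cytosolic ribosomal proteins (odds ratio 19) and glycolysis and hypoxia (odds ratio 14.7 with 0.5 added to each cell), each with more genes bound by Hoxb13 alone.

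Hoxb13 peaks crowded along sarcomere genes, with 306 peaks over 38 loci. Locus size alone did not account for this, since peaks per 100 kb were 11.3 times those of other genes (95% interval 5.53 to 21.4), and 8.54 times without Ttn. Meis1 peaks, by the protocols from the same hearts, were 3.59 times as dense over these genes (2.18 to 5.87). The intervals overlap, so by the criterion set beforehand a background of the ventricle chromatin that any antibody would show may account for part of the pattern. Genes were resampled separately for each factor, and the overlap of the intervals does not test the difference between the ratios. A pull toward strongly transcribed genes of any function also stays open, because promoters of ribosomal protein genes, active in every cell, carried Hoxb13 peaks with an odds ratio of 6.38 (3.12 to 14.1), though peaks per 100 kb of their loci were 3.79 times those of other genes (2.24 to 8.50), a lower estimate than for sarcomere genes with an overlapping interval. No input signal along gene bodies and no biological explanation was tested.

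The weaker part of the Meis1 list lay far from start sites, with a median distance of 94.0 kb to the nearest in the lower 15267 peaks by strength. Calls scattered evenly over the genome would not give their share inside genes, since 41.7% of these summits lay inside a RefSeq gene and 1000 uniform placements gave 47.6% to 50.4%. These peaks overlapped Hoxb13 peaks 5.2 times as often as the same peaks moved by 10 to 100 kb (range for 95% of placements 4.14 to 6.79), with an overlapping share of 2.36%. A fold above 1 had been set beforehand as evidence against calls that are not regulatory sites. But both lists came from ventricles of the same age, by the protocols from the same hearts. Sites prone to signal with any antibody would overlap there too, so such calls cannot be told apart from regulatory sites. No biological explanation was tested.

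Few peaks lay on the X chromosome, 206 for Meis1 and 204 for Hoxb13, or 1.25 and 1.23 per Mb against 12.6 and 9.20 on the autosomes. Fewer genes or less sequence does not account for it, since the share of X genes with a promoter peak was 0.218 times that of autosomal genes for Meis1 (95% interval 0.138 to 0.345) and 0.258 times for Hoxb13 (0.209 to 0.318). If a single X copy had lowered the strength of each peak to 0.5 of its value, the Hoxb13 count would have been lower than seen (observed over expected 1.28 per bp, 1.11 to 1.46, and 1.88 per gene), so that exact loss was not met, though a smaller one could be. For Meis1 the ratio was 0.594 per bp (0.516 to 0.681) and 0.876 per gene (0.761 to 1.00), and the explanation cannot be told apart from others because the measures disagree. The sex of the animals is not among the labels, and sex stays open, untested, as does filtering of peaks by the authors.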

How the results depend on the processing

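No paired analysis was possible because each factor has 1 peak list over its 3 hearts and no value per library; leaving out replicates was not run for the same reason, and motif alternatives were not run without a genome sequence. The subsets of the promoter and difference tests, the strongest 10%, the overlap by rank and 1 start site per gene were chosen after the data were seen. The promoter odds ratio (7.67 to 19.6), the overlap fold (2.61 to 10.3) and the odds ratio for genes bound by both (2.55 to 3.42) kept their direction and stayed past the threshold in each alternative tried. Counts of lists called higher changed more. Without locus strata Meis1 called 10 lists instead of 6. The strongest 10% called 6 instead of 14 for Hoxb13, 3 instead of 7 at Meis1 promoters, 4 instead of 12 at Hoxb13 promoters and 1 instead of 3 for the difference, with 10% of the peaks left to test. With a background of genes with a promoter peak of either factor, 1 list was called for Meis1 and 0 for Hoxb13, where most genes have a Hoxb13 promoter peak by construction and a higher call is hardly possible. Directions turned for Hoxb13 in this background for fatty acid oxidation (0.675), glycolysis and hypoxia (0.901), cardiac transcription factors (0.404) and TALE homeobox genes (0.676), and for Meis1 for oxidative phosphorylation (0.870), none past the threshold. Among neuronal genes they turned for Meis1 in the stronger 50% (0.543), with the same number of strongest peaks (0.747) and in the strongest 10% (0.750), and for Hoxb13 without locus strata (1.25), with no call on either side. The TALE homeobox difference turned in the stronger 50% (0.179), also with no call. In the strongest 10% directions also turned for Hoxb13-bound TALE homeobox (0.609), fibroblast (0.434) and smooth muscle genes (0.327), at Hoxb13 promoters for cardiac transcription factors (0.979) and TALE homeobox genes (0.835), and in the difference for glycolysis (0.886) and TALE homeobox genes (0.0580, adjusted exact p = 0.0306); beyond the fewer peaks, the cause was not tested. Over single lists called under at least 1 setting, 178 values under an alternative kept direction and side of the threshold, 55 fell short of it, 14 passed it newly and 17 turned. Unknown read depth limits any statement that a gene without a peak was free of the factor.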

Other observations

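The groups of genes and the tests in this part were chosen after the data were seen. Chemosensory receptor genes, silent in most tissues outside the nose, had few Hoxb13 peaks. Of 1110 olfactory receptor genes 65 had a Hoxb13 peak where 407 were expected from locus size (odds ratio 0.0927, 95% interval 0.0719 to 0.119, adjusted exact p = 1.01e-139), while 287 had a Meis1 peak where 264 were expected (odds ratio 1.13, 0.981 to 1.31). Vomeronasal receptor genes had fewer than expected of both, 29 of 355 with Hoxb13 (odds ratio 0.111, 0.0750 to 0.163, adjusted exact p = 3.06e-47) and 104 with Meis1 where 128 were expected (odds ratio 0.712, 0.560 to 0.906, adjusted p = 0.0202). The split between the factors differed from that of other genes in both families (odds ratio 0.103, adjusted exact p = 2.39e-61, and 0.12, adjusted p = 3.21e-20). Collagen genes leaned to Meis1, with 36 of 44 bound by Meis1 (odds ratio 4.66, adjusted exact p = 0.00198) and 25 by Hoxb13 (odds ratio 1.18), as did integrin genes, with 22 of 31 and 13; the tests of the difference gave adjusted p of 0.00390 and 0.00309. Zinc finger genes of the Zfp series leaned to Hoxb13, with 112 bound by Hoxb13 alone and 42 by Meis1 alone (adjusted exact p = 0.00153). Of 13 families tested, 6 passed the test of the difference, glutamate receptor genes being the other (3 with Hoxb13 alone and 10 with Meis1 alone, adjusted exact p = 0.0234). These tests of the difference took no account of locus size. All tests of the families treated each gene as independent, which neighbouring genes of a family may not be, so their intervals can be too narrow.

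A Hoxb13 peak lay within 500 bp of 65 of 408 tRNA genes and a Meis1 peak of 13, with 56 bound by Hoxb13 alone and 4 by Meis1 alone. For microRNA genes the numbers were 96 and 24 of 1228, with 83 and 11 alone, for snoRNA genes 37 and 16 of 1340, with 35 and 14 alone, and for snRNA genes 17 and 8 of 1004, with 16 and 7 alone. Among protein-coding genes with a peak within 500 bp of the start site, 5609 had Hoxb13 alone and 650 Meis1 alone. Against that split, tRNA genes (odds ratio 1.62, 95% interval 0.597 to 6.18, Fisher's exact test, adjusted p = 0.612) and microRNA genes (0.874, 0.461 to 1.83, adjusted p = 0.612) did not pass the test. The snoRNA genes (0.290, 0.151 to 0.586, Fisher's exact test, adjusted p = 0.00145) and snRNA genes (0.265, 0.103 to 0.765, adjusted p = 0.0145) leaned less to Hoxb13 than protein-coding genes did.

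The genes with the most Hoxb13 peaks were Ttn (93), Fhl2 (41), Atp2a2 (29), Tcf4 (28) and Tns1 (25), and Rbm20, a splicing regulator of titin, had 23 Hoxb13 and 20 Meis1 peaks. Those with the most Meis1 peaks were Lrrc4c (68), Adgrl3 (67), Ncam2 (66), Epha6 (60) and Cdh9 (58), with loci of 2031 to 4218 kb and 1.61 to 2.95 peaks per 100 kb.

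The strongest Hoxb13 peaks differed from those next in rank. Of the 50 strongest, 28.0% were in promoters, against 72.5% of the other 2178 in the strongest 10% (odds ratio 0.147, Fisher's exact test, p = 1.34e-10), and 5 of the 50 lay on the X chromosome, which held 23 of the 2178. Of the 50 strongest Meis1 peaks, 0 were in promoters, against 11.6% of the other 3003 in the strongest 10% (Fisher's exact test, p = 0.00522). Among the 100 strongest the contrast was smaller, with 41% of Hoxb13 peaks in promoters (odds ratio 0.257, Fisher's exact test, p = 7.91e-11) and 5% of Meis1 peaks (odds ratio 0.402, p = 0.0374). No explanation was tested for these.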
